A study of Mus musculus with 4 samples.

How the data were processed

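The samples were 4 libraries from bone marrow-derived macrophages of wild-type mice, seeded at 1000000 cells per well of 24-well plates, stimulated with LPS at 1 µg/ml for 1 h and cultured for 24 h with recombinant mouse galectin-1 or phosphate-buffered saline, per the labels' protocols. The dose of galectin-1 is not given in the sources used here. Total RNA was extracted on columns and libraries were made with a stranded poly(A) mRNA kit, per the labels' protocols. Groups and replicate numbers were taken from the sample titles.

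The authors deposited FPKM values, fragment numbers scaled to transcript length and to the mapped fragments of the library, at 1 value per gene symbol and library. The submitters' processing notes name TopHat2 2.0.13, Bowtie2 2.2.3, SAMtools 0.1.19 and Cufflinks 2.2.1 and the mouse build mm10, without their roles. The gene annotation, any filter on reads, the use of strand, the treatment of reads that map to several places and any normalization across libraries are not given in the sources used here. FPKM divides by transcript length, so entries for very short RNAs reach high values from few fragments, and values of near-identical genes or of overlapping genes on opposite strands depend on how reads were assigned. Poly(A) selection makes values of small RNAs without a poly(A) tail hard to interpret. Read counts were not used here, so no count model was fitted.

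Of the 23284 symbols, 23040 matched the symbols or synonyms of a RefSeq gene table for GRCm38.p6, the assembly of the mm10 build, which supplied the coordinates, counted from 1. Low genes below 0.3 FPKM were used to estimate relative depth. Of 1366 such genes, 259, 237 and 244 lay within 0.015, as a natural log, of the most frequent ratio, which a shared read number would give, for vehicle replicate 2, galectin-1 replicate 1 and galectin-1 replicate 2 against vehicle replicate 1. Only the ratio of depths can be had in this way, so intervals that need counts are not given.

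The values were used as deposited, as log2(FPKM + 1). Genes with a mean of at least 1 FPKM over the 4 libraries were tested, 9380 in all. The groups were compared with limma 3.58.1 in R 4.3.3, with empirical Bayes moderation, a trend of the variance with the mean, and a 2-sided Benjamini-Hochberg adjusted p under 0.05. The fit had 2 residual degrees of freedom and 3.89 prior degrees of freedom. A rank or permutation test of 2 against 2 libraries cannot go below a 2-sided p of 0.333, so none was used. Gene lists with at least 3 tested members, 34 of the 38 lists, were tested with camera on the same values, with its preset inter-gene correlation of 0.01 and, as an alternative, with a correlation estimated per list. The estimated version has the 2 residual degrees of freedom of the libraries and none of the lists passed it. Its lowest adjusted p was 0.625. For macrophage identity (-0.07) and clearance of dying cells and complement (-0.02) the estimate lay below the preset, so a higher correlation is not what ended those calls. It lay above the preset for inflammatory cytokines (0.115), glycolysis and hypoxia (0.188) and ribosomal proteins (0.303). The same held for anti-inflammatory mediators and the interleukin 10 response (0.0287) and for the lysosome (0.0133). There a higher correlation and the few degrees of freedom cannot be told apart. Of 700 list symbols, 681 were found in the files directly or under another symbol.

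The groups, tests, gene lists, single genes and the rule for named genes were fixed before the data were examined. The rule named 10 single genes always. It named the 10 highest and 10 lowest log2 fold changes among genes past the threshold whose groups did not overlap, leaving out gene models with a Gm, LOC or Rik symbol. It named up to 4 members of smallest p from each list that had a call or a member past the threshold, and up to 2 from each other list. Not every gene the rule allows is printed. Genes at least 2-fold apart without overlap were counted as a description.

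The replicates were compared before they were averaged. Pearson correlations of log2 values were 0.983 between the vehicle libraries, 0.988 between the galectin-1 libraries and 0.979 to 0.986 across groups. Small RNA entries accounted for much of the spread: without them the correlations within the groups were 0.997 and 0.998. Without them the first principal component held 56.9% of the variance and separated the groups. With all tested entries it held 44.8%, and vehicle replicate 2 (score -2.04) lay nearer to galectin-1 replicate 1 (8.87) than to vehicle replicate 1 (-22.8). No libraries held identical values.

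The test was tried on simulated data made from the real means and the moderated spreads of the 9380 genes. Noise was normal and independent between genes, with 2 libraries per group and 200 changed genes in each of 20 simulations. It recovered 29.1% of genes changed by 0.25 on the log2 scale, 77.9% at 0.5 and 99.0% at 1, and 6.04% of the calls were false. Moderated spreads are more alike than the spreads of single genes, so recovery in the real data may be lower. With nothing changed, a mean of 1.5 genes and 0 lists were called. The 0 lists say nothing about lists whose members vary together, and the estimated correlation of the called ribosomal protein list was 0.303.

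Alternatives were pseudocounts of 0.1 and 0.5, no filter, a minimum mean of 5 FPKM, median-ratio scaling, quantile normalization, limma without the trend or with robust moderation, the replicate number as a block, each library left out, and an adjusted p under 0.1. With a library left out, the lone library of its group was assumed to vary like those of the other group. A fit without the 42 small RNA entries (symbols of microRNAs, small nucleolar, small nuclear and Y RNAs) was added after seeing the data. Near-identical transcripts of Ndufs5 and Mir682 were sought with BLAST 2.17.0 among the reference transcripts, at 95% identity or more. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.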

Results

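RNA sequencing was carried out on mouse bone marrow-derived macrophages, cells grown from bone marrow that serve as a primary culture model of tissue macrophages. All cultures first received lipopolysaccharide (LPS), the bacterial cell wall component sensed by Toll-like receptor 4, at 1 µg/ml for 1 h. They were then kept for 24 h with recombinant mouse galectin-1, a galactoside-binding lectin, or with phosphate-buffered saline as the vehicle. Each group had 2 libraries, and no library without LPS was analysed here. The deposited values were FPKM for 23284 gene symbols, with library totals of 553191 and 541138 FPKM for vehicle replicates 1 and 2 and 557661 and 555507 FPKM for galectin-1 replicates 1 and 2. Between 13636 and 13785 symbols lay above 0 in a library. The FPKM steps of low genes gave depths of 0.969, 1.03 and 0.872 for vehicle replicate 2, galectin-1 replicate 1 and galectin-1 replicate 2 relative to vehicle replicate 1; the absolute depth is unknown.

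The design implied a single comparison, galectin-1 against vehicle in LPS-stimulated macrophages, which asks how the lectin alters the character of macrophages; the series examined galectin-1 for an anti-inflammatory role in colitis. With galectin-1 the transcript of the inflammasome cytokine Il1b fell from 372 ± 1.51 to 264 ± 3.90 FPKM (SD, n = 2 per group), a log2 fold change of -0.50 with a standard error of 0.03 (limma, adjusted p = 0.00612). Il12b, the p40 subunit of interleukins 12 and 23, fell from 20.8 ± 0.455 to 13.5 ± 1.43 FPKM (log2 fold change -0.59, standard error 0.08, adjusted p = 0.0432). Il10, which encodes the main anti-inflammatory cytokine of macrophages, rose from 63.7 ± 1.94 to 81.4 ± 2.55 FPKM (0.35, standard error 0.04, adjusted p = 0.0374). The zinc importer gene Slc39a10 had 4.48 ± 0.226 FPKM with vehicle and rose to 10.6 ± 0.655 (1.08, standard error 0.07, adjusted p = 0.0126). Neat1, a long non-coding nuclear RNA listed among the signs of RNA quality, fell from 102 ± 6.58 to 44.5 ± 0.550 FPKM (-1.17, standard error 0.05, adjusted p = 0.00174). In all, 57 genes were higher and 55 lower with galectin-1 among 9380 tested, and 2172 had an unadjusted p under 0.05. Most of the 112 calls were small: 97 lay under 1.5-fold, and their median absolute log2 fold change was 0.37.

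The groups of all 112 called genes did not overlap, as was the case for 55.4% of the tested genes, where chance gives 33.3%. Fold changes are differences of log2(FPKM + 1), a scale that understates the change of low genes. Nothing in the labels says that the libraries came from separate cultures or animals, so the p-values measure only the spread between these samples, which may be technical. The calls depended on having all 4 libraries: 4 genes were higher and 12 lower without vehicle replicate 1, 5 and 8 without vehicle replicate 2, 8 and 5 without galectin-1 replicate 1, and 9 and 3 without galectin-1 replicate 2. Few of the 112 called genes passed in those fits. All 112 kept their sign in each, which groups without overlap ensure in advance. Neat1 passed without any of the libraries, with adjusted p from 0.00268 to 0.0202. Il1b passed in 3 of these 4 fits and had an adjusted p of 0.0553 without vehicle replicate 2. Quantile normalization made 24 genes higher and 47 lower, so that 33.8% of the calls were increases in place of 50.9%. In limma without the trend, Neat1 (adjusted p = 0.0792) and Il1b lost their calls, as did all but the small RNA entries Mir682 and Mir3074-1.

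**Figure D1:**
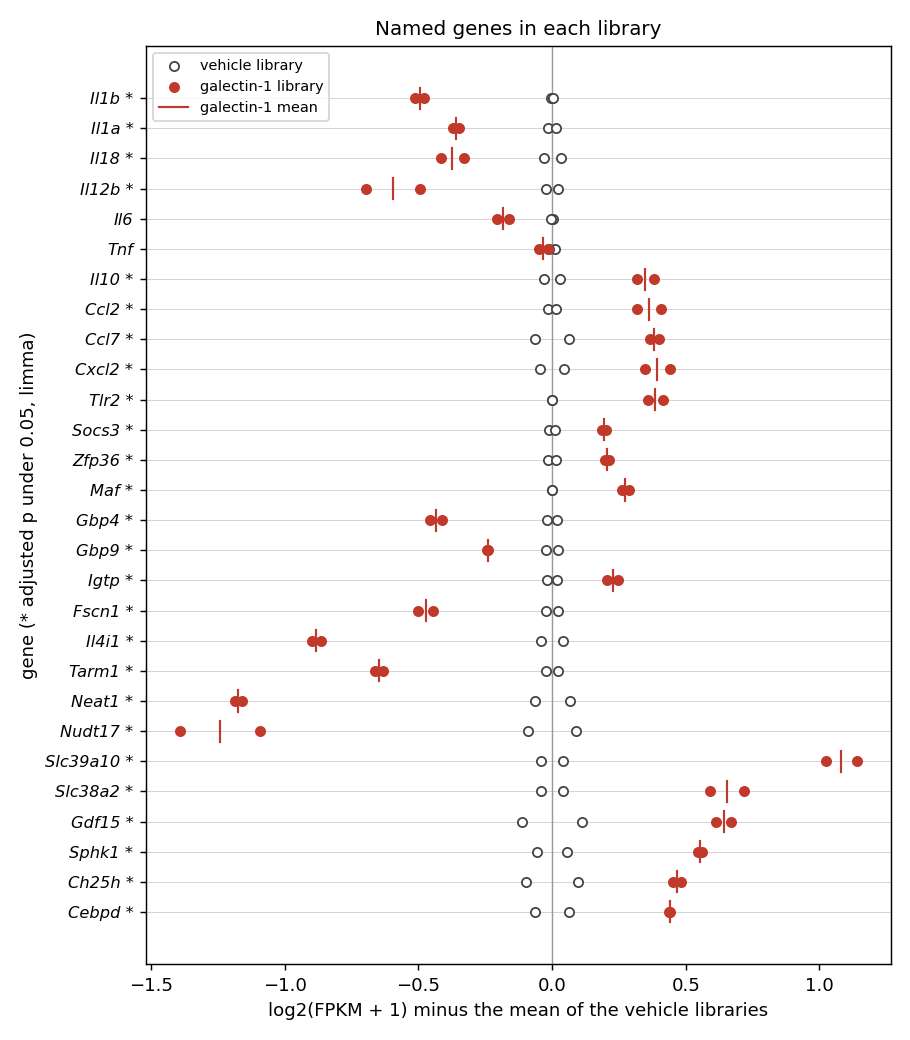
Each point is a library, placed by its log2(FPKM + 1) minus the mean of the vehicle libraries for that gene; open points are vehicle, red points galectin-1 and the red line the galectin-1 mean (n = 2 per group). An asterisk marks an adjusted p under 0.05 in limma. Il1b lies 0.50 below vehicle and Slc39a10 lies 1.08 above it, while the Tnf mean lies 0.03 below it, a difference that did not pass.

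Of the inflammatory cytokines, 17 of 20 listed genes were tested; 4 fell, none rose and 13 did not pass. Besides Il1b and Il12b these were Il1a, the other interleukin 1 gene, from 119 to 92.4 FPKM (log2 fold change -0.36), and Il18, whose product the inflammasome also processes, from 49.5 to 38.0 FPKM (-0.37). The cytokine count was 1 higher and 7 lower when adjusted over the list alone. Counts over a list alone, here and below, are to be read beside the 2172 of 9380 tested genes with an unadjusted p under 0.05 in limma. Differences were negative for 14 of the 17, with a median of -0.09, and camera with its preset correlation called the list lower (adjusted p = 0.00161). The adjusted p was 0.625 with an estimated correlation. The median was -0.14 without vehicle replicate 1 and -0.04 without vehicle replicate 2. Tnf, the prototype LPS-induced cytokine, had 831 ± 8.53 FPKM with vehicle and 813 ± 14.1 with galectin-1 (-0.03, standard error 0.03, adjusted p = 0.520), so no difference beyond the replicate spread was found. Il6 had 294 ± 1.49 and 259 ± 5.42 FPKM (-0.18, standard error 0.03) and missed the threshold with an adjusted p of 0.0562.

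Among the genes of classical activation, the LPS and interferon-driven inflammatory state, Il12b was the member that passed, and 19 of 20 tested did not. Adjusted over the list alone, 3 were higher and 6 lower, and camera gave an adjusted p of 0.157; the list was called lower after quantile normalization (adjusted p = 0.0425). The costimulatory genes Cd40 and Cd80 had log2 fold changes of -0.19 and -0.38 with adjusted p of 0.0505 and 0.0568. The inducible nitric oxide synthase gene Nos2 had 156 FPKM with vehicle and 169 with galectin-1 (0.12, adjusted p = 0.102).

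Of 18 tested chemokine genes, Ccl2 and Ccl7, which encode attractants of monocytes, and Cxcl2, which encodes an attractant of neutrophils, rose; the other 15 did not pass. Ccl2 went from 618 ± 9.80 to 795 ± 34.9 FPKM (log2 fold change 0.36), Ccl7 from 774 to 1008 FPKM (0.38) and Cxcl2 from 191 to 251 FPKM (0.39), with adjusted p from 0.0312 to 0.0374. There were 8 higher and 4 lower chemokine genes adjusted over the list alone. Ccl24, encoding an eosinophil attractant, had 3.68 FPKM with vehicle and 2.05 with galectin-1 (-0.62, adjusted p = 0.0589). The list was not called (camera adjusted p = 0.613). Its median was -0.02 while camera pointed upward, and the median was positive without vehicle replicate 2 (0.02) or galectin-1 replicate 1 (0.01). Ccl2 and Ccl7 are near relatives, as are several genes of this family, and how the deposited values divide reads between relatives is not given in the sources used here. Quantile normalization ended the call of Cxcl2 (adjusted p = 0.0551) and kept its direction.

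Of 25 tested genes of Toll-like receptor signalling, Tlr2, the receptor of bacterial lipoproteins, rose from 132 ± 0.165 to 173 ± 4.65 FPKM (0.39, adjusted p = 0.0237) and 24 did not pass; adjusted over the list alone, 7 were higher and 2 lower (camera adjusted p = 0.128). Of 21 NF-kB feedback genes, Zfp36, whose product promotes the decay of cytokine mRNAs, rose from 698 to 806 FPKM (0.21, adjusted p = 0.0432), and 20 did not pass. Adjusted over this list alone, 2 were higher and 5 lower, and camera gave an adjusted p of 0.678. Zfp36 lost its call after quantile normalization, with an adjusted p of 0.106.

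The list of anti-inflammatory mediators and the interleukin 10 response held 19 tested genes, of which 2 rose, none fell and 17 did not pass. Il10 was accompanied by Socs3, a feedback inhibitor of cytokine receptors, which went from 641 to 734 FPKM (0.19, adjusted p = 0.0446). Of these genes, 5 were higher and none lower adjusted over the list alone. Sbno2 and Nfil3, known targets of interleukin 10 signalling, had log2 fold changes of 0.20 each with adjusted p of 0.0555 and 0.0676. Camera called the list higher with the preset correlation (median 0.07, adjusted p = 0.00420), and the adjusted p was 0.625 with an estimated correlation. The median was 0.10 without galectin-1 replicate 1. Quantile normalization ended that call (adjusted p = 0.0619) and the call of Socs3 (adjusted p = 0.0690). Tgfb1, encoding another anti-inflammatory cytokine, had 87.3 ± 4.49 and 91.7 ± 4.26 FPKM (0.07, adjusted p = 0.463).

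Of 16 tested genes of macrophage identity, Maf, a transcription factor of resident macrophages, rose from 88.7 ± 0.112 to 107 ± 1.47 FPKM (0.27, adjusted p = 0.0371) and 15 did not pass; adjusted over the list alone, 7 were higher and none lower. Differences were positive for 14, with a median of 0.09; the growth factor receptor gene Csf1r had a log2 fold change of 0.15 and the lysozyme gene Lyz2 of 0.13, with adjusted p of 0.0614 and 0.0694. Camera gave an adjusted p of 0.00194 with the preset correlation, and the adjusted p was 0.625 with an estimated correlation. The list for clearance of dying cells and complement had 19 tested genes. Its member C3ar1, the receptor of complement fragment C3a, rose from 337 to 385 FPKM (0.19, adjusted p = 0.0453), and 18 did not pass. Adjusted over the list alone, 2 were higher and none lower. Its camera call (adjusted p = 0.0227) was lost with an adjusted p of 0.625 with an estimated correlation. It was also lost without vehicle replicate 1 (adjusted p = 0.0566), vehicle replicate 2 (0.0594) or galectin-1 replicate 2 (0.0589), at a mean of at least 5 FPKM and in limma without the trend. Quantile normalization ended it too (0.159), as it did the call of C3ar1 (0.0669).

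Camera called 3 further lists higher in which no member passed in limma. The lysosome list had a median log2 fold change of 0.06 with 23 of 26 positive (adjusted p = 0.00194), and the adjusted p was 0.625 with an estimated correlation. Ctsl, a cathepsin protease, had 661 and 731 FPKM (0.15, adjusted p = 0.0614), and Npc1, a lysosomal cholesterol transporter, had 22.4 and 26.9 FPKM (0.25, adjusted p = 0.0777). The glycolysis and hypoxia list had a median of 0.09 with 19 of 22 positive (adjusted p = 0.00194), and the adjusted p was 0.714 with an estimated correlation. Gpi1, a glycolytic isomerase, had 100.5 and 113 FPKM (0.16, adjusted p = 0.0690). The ribosomal protein list had a median of 0.06 with 23 of 24 positive (adjusted p = 0.00161), and the adjusted p was 0.732 with an estimated correlation. Rps19 had 663 and 717 FPKM (0.11, adjusted p = 0.111). Unadjusted p under 0.05 in limma was found for 6 of 26, 9 of 22 and 5 of 24 members of these lists, all positive. Over all tested genes it was found for 2172 of 9380. Adjusted over each list alone, 2 lysosome, 2 glycolysis and 0 ribosomal genes were higher. The ribosomal call was lost without vehicle replicate 2 (adjusted p = 0.0594) or galectin-1 replicate 1 (0.0505), where its median was 0.03, and quantile normalization ended the lysosome and ribosomal calls (adjusted p = 0.159 for the lysosome). The medians stayed positive under both other scalings.

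Interferon-dependent genes moved both ways. Of 14 tested interferon-induced GTPases, guanylate-binding and immunity-related proteins that act against intracellular pathogens, Gbp4 fell from 158 ± 3.05 to 117 ± 2.60 FPKM (-0.43, adjusted p = 0.0179) and Gbp9 fell from 209 to 177 FPKM (-0.24, adjusted p = 0.0446). Igtp rose from 346.4 to 405.5 FPKM (0.23, adjusted p = 0.0446), and 11 did not pass. The GTPase count was 4 higher and 8 lower adjusted over the list alone, and camera gave an adjusted p of 0.117. The genes of this family lie in clusters of close relatives, so that reads may be divided between them. Quantile normalization ended the call of Igtp (adjusted p = 0.0871) and called the list lower (adjusted p = 0.0425). Of 32 interferon-stimulated genes, Xaf1, encoding a pro-apoptotic factor, fell from 90.4 to 77.1 FPKM (-0.23, adjusted p = 0.0477), and 31 did not pass. Adjusted over that list alone, 6 were higher and 5 lower (camera adjusted p = 0.839).

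**Figure D2:**
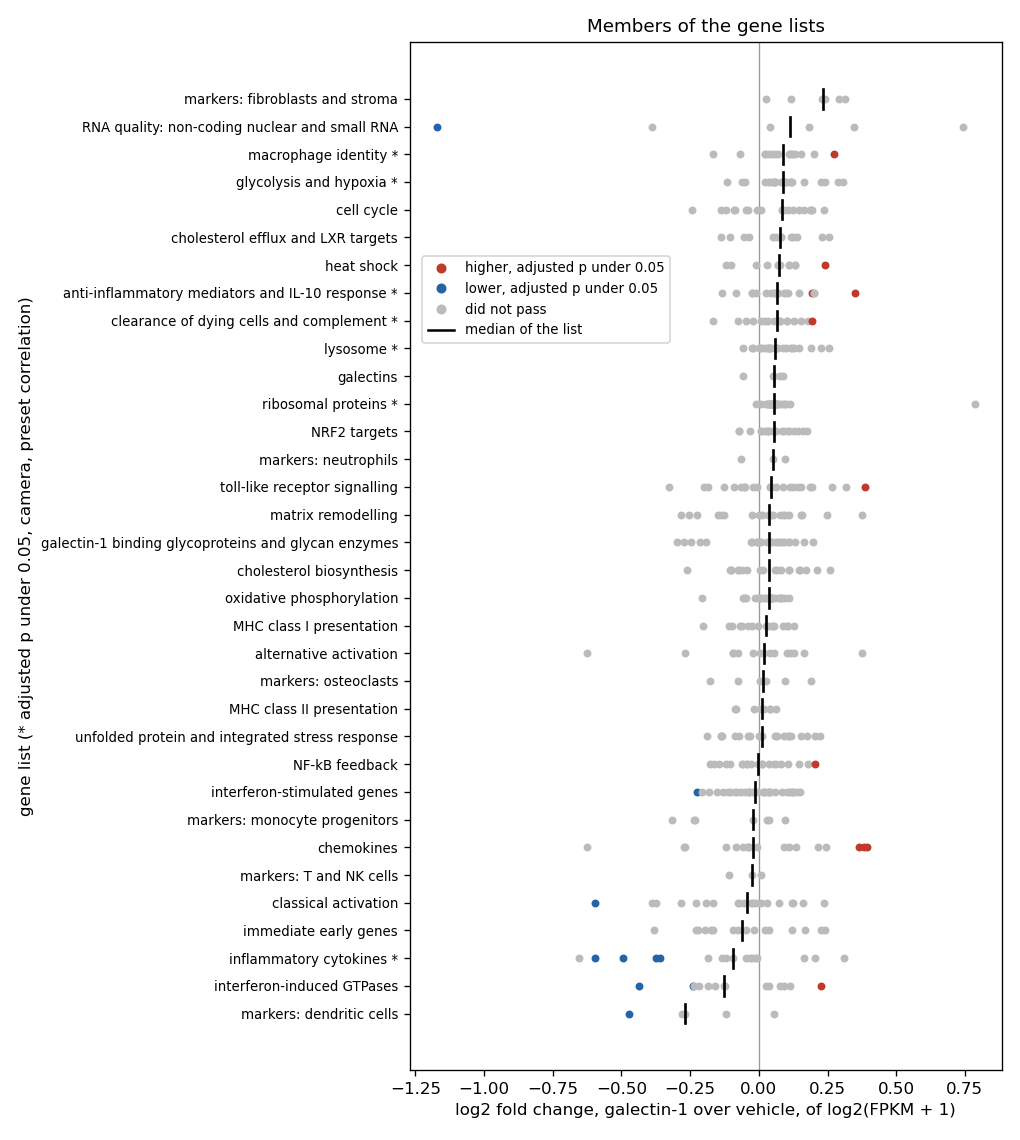
Each point is the log2 fold change of a tested list member (galectin-1 over vehicle, log2(FPKM + 1), 2 libraries per group), red or blue where it passed limma at an adjusted p under 0.05 and grey where it did not; black bars are list medians and asterisks mark camera calls with the preset correlation. The medians of the called lists lie between -0.09 for inflammatory cytokines and 0.09 for macrophage identity, and none of these calls was kept with an estimated correlation.

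Markers of other cells and signs of RNA quality were measured beside these groups. Of 13 dendritic cell markers, 5 were tested, and Fscn1, the actin-bundling protein of mature dendritic cells, fell from 11.5 ± 0.256 to 8.01 ± 0.245 FPKM (-0.47, adjusted p = 0.0425). Ccl22 had 9.04 and 7.34 FPKM (-0.27, adjusted p = 0.0911). Adjusted over the list alone, 2 were lower; the median was -0.27 and the camera adjusted p 0.0503, or 0.0451 in a fit without small RNA entries chosen after the data were seen. Of the 5 differences, 4 were negative, as were most of those of the inflammatory cytokines, and Itgax, an integrin, had 0.06. The 6 tested fibroblast markers were all positive, with a median of 0.24 (0.16 without galectin-1 replicate 1) and none past the threshold (1 at an unadjusted p under 0.05; camera adjusted p = 0.0823). The fibroblast list was called higher after quantile normalization (adjusted p = 0.0425) and in limma without the trend. Bgn, a matrix proteoglycan, had 5.57 and 7.18 FPKM (0.31, adjusted p = 0.120), and the direction of these markers was that of the lists called higher. Among 6 tested nuclear and small non-coding RNAs, Neat1 fell and 5 did not pass; adjusted over the list alone, 2 were lower. Malat1, the neighbouring nuclear RNA on chromosome 19, had 95.4 ± 1.21 and 72.8 ± 8.34 FPKM (-0.39, adjusted p = 0.0694). Whether recovery of nuclear RNA or its capture by poly(A) selection differed between the groups was not tested, so the decrease of Neat1 may be technical. The list of nuclear and small non-coding RNAs had a median of 0.11 while camera pointed downward (adjusted p = 0.613). The median was -0.01 without vehicle replicate 1, 0.19 without vehicle replicate 2 and 0.07 without galectin-1 replicate 2, and none of the 13 mitochondrially encoded genes was found under the symbols used.

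Further marker lists had no member past the threshold. The camera adjusted p was 0.583 for monocyte progenitors (7 tested), 0.839 for neutrophils (3 tested), 0.678 for T and NK cells (3 tested) and 0.909 for osteoclasts (6 tested). For neutrophils the median was 0.05 with a camera direction downward, and it was negative without vehicle replicate 2 (-0.02) or galectin-1 replicate 1 (-0.11). It was 0.13 without vehicle replicate 1 and 0.22 without galectin-1 replicate 2. For B cells 2 genes, for erythroid cells 1 gene and for mast cells, basophils and eosinophils 0 genes reached the expression minimum, so these lists were not tested.

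Of 12 tested heat shock genes, the chaperone gene Hsp90aa1 rose from 97.5 to 115 FPKM (0.24, adjusted p = 0.0446) and 11 did not pass; adjusted over the list alone, 3 were higher (camera adjusted p = 0.0823). The call of Hsp90aa1 was lost after quantile normalization, at an adjusted p of 0.0617, and the list was called higher without galectin-1 replicate 1 (adjusted p = 0.0434) and with no filter. No member of the following lists passed. Alternative activation, the interleukin 4-driven state, had a camera adjusted p of 0.722 (15 tested); Mrc1, its mannose receptor, had 67.2 ± 0.908 and 75.3 ± 0.803 FPKM (0.16, adjusted p = 0.0831). Arg1, encoding arginase 1, was near the floor at 0.201 ± 0.0362 and 0.0925 ± 0.0530 FPKM and was not tested. The camera adjusted p was 0.946 for MHC class II presentation, where the median of 0.01 and the camera direction differed in sign (median -0.01 without vehicle replicate 1 and -0.03 after quantile normalization), and 0.923 for MHC class I presentation. It was 0.625 for cholesterol biosynthesis, 0.138 for cholesterol efflux and LXR targets, 0.344 for oxidative phosphorylation, 0.408 for cell cycle genes and 0.613 for the unfolded protein and integrated stress response, whose regulator Atf4 had 85.8 and 100.3 FPKM (0.22, adjusted p = 0.0614). It was 0.0914 for NRF2 targets, a list called higher without vehicle replicate 1 (0.00920; 0.622 without vehicle replicate 2). It was 0.868 for matrix remodelling (median 0.04, camera direction downward) and 0.635 for immediate early genes. The galectins gave 0.344, and galectin-1 binding glycoproteins and glycan enzymes gave 0.654 with a median of 0.04 and a mean of -0.003. Lgals1, the gene of galectin-1 itself, had 771 ± 10.1 and 814 ± 30.5 FPKM (0.08, standard error 0.03, adjusted p = 0.243). Adjusted over each list alone, 3 genes were higher and 2 lower in alternative activation, 3 higher and 2 lower among immediate early genes, 1 higher and 4 lower in matrix remodelling, 1 lower in MHC class I presentation and 1 higher in the stress response. Over the 23 lists with a tested member and none past the threshold in limma, 72 of 317 genes had an unadjusted p under 0.05. That share was similar to the 2172 of all 9380 tested genes.

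Of the 10 single genes fixed before the values were examined, 9 were tested. Adjusted over the list alone, Il1b (2.35e-05), Il10 (0.000782), Il12b (0.000782), Il6 (0.00207), Mrc1 (0.00630) and Nos2 (0.00999) passed. Lgals1 (0.0818), Tgfb1 (0.259) and Tnf (0.284) did not.

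The genes with the largest increases also included Slc38a2, a neutral amino acid transporter, from 8.17 ± 0.379 to 13.4 ± 0.902 FPKM (0.65), and the stress cytokine Gdf15, from 51.7 ± 5.80 to 81.0 ± 2.33 FPKM (0.64). Sphk1, which makes sphingosine 1-phosphate, rose from 7.88 to 12.0 FPKM (0.55). Ch25h, the cholesterol 25-hydroxylase of activated macrophages, rose from 40.7 to 56.6 FPKM (0.47), a call lost after quantile normalization (adjusted p = 0.0629). The transcription factor gene Cebpd rose from 65.4 to 88.9 FPKM (0.44), Heca from 9.33 to 13.3 FPKM (0.47) and Phf23 from 26.6 to 36.4 FPKM (0.44). Their adjusted p lay between 0.0351 and 0.0453. On assembly GRCm38, the build named mm10 in the labels, Slc39a10 lies on chromosome 1 from 46807544 to 46925776 and Il10 on the same chromosome from 131019845 to 131024970.

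Among the largest decreases, Nudt17, a nucleotide hydrolase gene, fell from 10.95 ± 1.05 to 4.07 ± 0.746 FPKM (-1.24, adjusted p = 0.0276). Il4i1, a secreted amino acid oxidase that restrains T cells, fell from 12.4 ± 0.529 to 6.28 ± 0.119 FPKM (-0.88, adjusted p = 0.0128). Tarm1, an activating receptor of myeloid cells, fell from 38.6 ± 0.862 to 24.3 ± 0.355 FPKM (-0.65, adjusted p = 0.0116). Tnfrsf14, the herpesvirus entry mediator, fell from 32.7 to 20.4 FPKM (-0.65), Inpp1, an inositol phosphatase, from 6.02 to 3.29 FPKM (-0.71), Polm, a DNA polymerase, from 4.42 to 2.50 FPKM (-0.63), and Rnaseh1, a ribonuclease of RNA and DNA hybrids (-0.58). The call of Inpp1 was lost after quantile normalization (adjusted p = 0.0551). Neat1 lies on chromosome 19 from 5824708 to 5845480, Il1b on chromosome 2 from 129364569 to 129371164, and Il12b on chromosome 11 from 44400063 to 44414677.

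The entries furthest apart were uncertain. Mir682, on chromosome 13 from 75645046 to 75645141, was listed at 0 in both vehicle libraries and at 133 and 158 FPKM with galectin-1. Mir3074-1 was listed at 487 and 1004 FPKM with vehicle and at 0 in both galectin-1 libraries. Ndufs5, a subunit of respiratory complex I, had 0.0208 and 0.0103 FPKM with vehicle and 9.31 and 18.9 with galectin-1. Its transcript has a near-identical processed pseudogene, and no tested gene of the oxidative phosphorylation list passed (2 of 25 at an unadjusted p under 0.05). Of all tested entries, 44 were at least 2-fold apart, 33 of them small RNA entries. Without overlap between the groups, 13 were 2-fold apart, 8 higher and 5 lower, and 7 of these passed the test. Each of the 4 fits without a library had more, with 28 and 22 without vehicle replicates 1 and 2 and 32 and 22 without galectin-1 replicates 1 and 2, since a lone library overlaps less often.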

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

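The fit without small RNA entries was chosen after the data were seen. Without those 42 entries, 189 genes were higher and 176 lower, and all 110 of the other calls were kept. Il6 then passed (adjusted p = 0.0282; 0.0266 to 0.231 over its alternatives). The count of 57 higher and 55 lower became 1 and 2 with no filter and 1 and 1 without the trend. The calls without the trend were the small RNA entries Mir682 and Mir3074-1, and with no filter Neat1 passed as well. The count was 127 and 99 at a mean of at least 5, and 197 and 183 with robust moderation. It was 302 and 289 at an adjusted p under 0.1, and 24 were higher with quantile normalization. Leaving out each library gave 4 to 9 higher and 3 to 12 lower. The called genes kept their sign in all of these fits where they were tested. Since their groups did not overlap, only quantile normalization among these fits could have turned a sign. Fewer libraries were the construction of the last fits, and otherwise the cause of the changed counts was not tested. Deviations of same-numbered libraries correlated at 0.01 (0.04 without small RNA entries, 0.13 for the other genes with a mean of at least 10 FPKM), and no label ties the numbers to a shared preparation, so they were not treated as pairs; the fit with the replicate block gave 123 higher and 117 lower genes and 2 lists lower. Called lists, 6 higher and 1 lower, became 0 and 0 with an estimated correlation and 3 and 3 with quantile normalization, where classical activation, the GTPases and the fibroblast markers joined; 2 were lower with pseudocounts of 0.1 or 0.5, at a mean of at least 5, and without small RNA entries, where the dendritic cell markers joined. The 13 genes 2-fold apart without overlap became 23 with a pseudocount of 0.1 and 22 to 32 with a library left out. No called gene among those named changed sign, and the uncalled Ctss, Mmp8, Il7r and Cd79b did in 1 or 2 fits each. Relative depth ranged from 0.872 to 1.03, and absolute depth is unknown, so the counting error of low genes is not known.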

Other observations

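The patterns and tests in this part were chosen after the values were seen, and so were the genes outside the fixed lists and fixed single genes; both rescalings were fixed beforehand. Called genes outside the lists are given here as single genes, picked by hand. The actin crosslinker gene Flna fell from 149 ± 5.40 to 122 ± 0.482 FPKM (log2 fold change -0.29, n = 2 per group). Zyx, a focal adhesion protein, fell from 288 to 239.5 FPKM (-0.27), and Csrp1, a LIM-domain protein that binds actin filaments, from 124 to 95.7 FPKM (-0.37). Their adjusted p in limma lay between 0.0232 and 0.0432. Other called genes of cytoskeletal proteins rose, such as the tubulin gene Tubb4b (0.34), Trip10 (0.29) and Sept11 (0.27), and no cytoskeletal list was tested for enrichment.

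The costimulatory ligand gene Tnfsf4 went from 69.8 to 54.9 FPKM (-0.34), Il15ra, the receptor subunit that presents interleukin 15, from 160 to 136 FPKM (-0.23), and Fcgr2b, the inhibitory Fc receptor, from 227 to 190 FPKM (-0.25). The adenosine receptor gene Adora2a went from 28.1 to 21.2 FPKM (-0.39). Receptor genes went both ways: besides Tlr2 and C3ar1, Cd180, a relative of Toll-like receptor 4, rose from 180 to 215 FPKM (0.25). The kinase genes Map2k3 and Mapkapk3 of the p38 pathway rose from 39.9 to 51.1 FPKM (0.35) and from 34.7 to 42.6 FPKM (0.29). Sat1, which acetylates polyamines, rose from 387 to 512 FPKM (0.41), and Mat2a, which makes S-adenosylmethionine, from 45.5 to 59.9 FPKM (0.39). Atp6v0c, a proton pump subunit with near-identical pseudogenes, had 211 and 132 FPKM with vehicle and 81.3 and 66.6 with galectin-1 without passing (adjusted p = 0.0656).

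Il1b, Il1a, Il12b and Il18 were lower while Il10, Ccl2, Ccl7, Cxcl2 and Tlr2 were higher. Library scaling was tested on Il1b and Il10. Median-ratio scaling left Il1b at -0.50, but with factors of 0.998 to 1.003 it could move little. Quantile normalization gave -0.53 for Il1b and 0.31 for Il10, which argues against scaling for these genes. The other named genes kept their direction after quantile normalization, and Cxcl2 lost its call (limma adjusted p = 0.0551). Endotoxin carried with the recombinant protein would add to the LPS stimulus and go with the group; for the higher genes it stays open, since the LPS-induced Tnf, at -0.0325 (standard error 0.03), can be saturated, and for the lower cytokines the data offered no test that decides on it. Fewer dendritic cells may account for part of the decreases, but the markers cannot decide on it, since only 5 of 13 reached the expression minimum. Ccl22 is also in other lists, and activated macrophages can express the 5 tested markers. Their median was -0.27, close to the bound of -0.30 set from Il12b. The standard error of their mean, 0.09, came from the spread over the 5 genes and not between libraries. Of the 5, 4 were negative, with Fscn1 the most abundant at 11.5 and 8.01 FPKM, while Itgax had 1.66 and 1.76 FPKM (0.06). An effect of galectin-1 on macrophages stays open too.

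The largest changes came from small RNA entries and Ndufs5, and Gm9781 had the same pattern (0.00155 and 0.00143 FPKM with vehicle, 2.04 and 3.08 with galectin-1), while Amd1 (0.0380 and 8.47) and Rnaset2a (0.00336 and 4.20) differed as widely between the vehicle libraries; these 3 were picked after the values were seen. Libraries of the same group were 2-fold or more apart for 88.1% of the 42 small RNA entries and for 0.171% of the 9338 others, in line with few reads on very short entries. The Mir682 entry was 98.96% identical over its 96 bases to a transcript of the ribosomal protein gene Rpl37a, so reads may be shared. Rpl37a had 736 and 701 FPKM with vehicle and 722 and 747 with galectin-1. The identity is the same for every library, so it cannot say why the entry was at 0 with vehicle alone. A division of reads between Ndufs5 and its pseudogene BC002163, 99.4% identical over 319 bases, is argued against by the sum of both entries, which still differed by 5.75 on the log2 scale. The Ndufs5 values of 0.0208 and 0.0103 FPKM with vehicle are implausible for a complex I gene, 8 others having vehicle means above 10 FPKM, so a failed estimate, copies outside the reference transcripts and a change of the gene itself all stay open.

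Slc39a10, a zinc importer, was higher and Mt2, a metallothionein induced by zinc, fell from 771 ± 48.6 to 567 ± 28.3 FPKM (-0.44, adjusted p = 0.0396). A candidate explanation is less zinc in the galectin-1 cultures, though the data used here held no zinc measurement. Other causes of the lower Mt2 were not tested. Slc30a1, a zinc exporter that zinc induces, had 6.56 ± 0.789 and 4.61 ± 0.00872 FPKM (-0.43, standard error 0.09), in line with it though not past the threshold (adjusted p = 0.0839), and Mt1 had -0.15 (adjusted p = 0.0848). A single deviating library is argued against by the lowest value of Slc39a10 with any library left out, 1.02, although its adjusted p then lay at 0.0566 without vehicle replicate 1, 0.0695 without vehicle replicate 2, 0.0696 without galectin-1 replicate 1 and 0.0626 without galectin-1 replicate 2. Whether the protein, its buffer or the cells set zinc availability was not tested, since the preparation was given to all galectin-1 cultures and no vehicle culture.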
